A study of Homo sapiens with 11 samples.

How the data were processed

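Total RNA of PANC-1 cells, an established human pancreatic cancer line, was sequenced in 11 libraries from 2 knockdown experiments. One table covers 3 libraries of cells given a control silencer and 3 given a silencer against the long non-coding RNA RUNX1-IT1. The other covers 3 libraries with a control hairpin vector (sh-NC) and 2 with a hairpin vector against RUNX1 (sh-RUNX1). Per the submitters' processing notes, HISAT2 2.0.4, Cufflinks 2.1.1, Cuffdiff and the hg38 build were used, with no role or order given. The annotation release, the tool that counted reads and the strandedness of the libraries are not stated, so reads of antisense or overlapping genes cannot be assigned to a strand, and levels of close paralogs and pseudogenes are uncertain.

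Per the file headers, the silencer table deposited by the authors holds whole-number read counts and FPKM per gene for each library. The values of the sh-RUNX1 table deposited by the authors carry no unit in the header. They were read as FPKM, since each value times the listed gene length is a whole multiple of 1 step per library, within 0.02 reads for 99.97% of the values above 0. The sums also showed that the authors had scaled these libraries to one another. The tables list 50868 and 58302 genes, of which 50356 are in both. They were normalized separately, so every test was made within a table and only fold changes were compared between them.

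The silencer libraries hold 13151373 to 19040332 reads assigned to genes. The sh-RUNX1 experiment holds 20723276 to 24419985 per library, as recovered from FPKM times length. A gene with no reads in a group was given a floor of 3 reads over the summed reads of the group. In a single silencer library 3 reads correspond to 0.158 to 0.228 CPM, and over the group to less. Floors cover counting error only.

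Before the data were examined, the groups, tests, alternatives, gene lists and the rule for named genes were fixed. Silencer counts were tested with edgeR 4.0.16 in R 4.3.3, using TMM scaling, its default filter on low counts (minimum count 10) and the quasi-likelihood F test. The sh-RUNX1 values were tested with limma 3.58.1 with a variance trend on log2(FPKM + 1), over genes with a mean of at least 1 FPKM in a group. All tests were two-sided, with Benjamini-Hochberg adjustment at 0.05 within a comparison. Levels are CPM in the silencer experiment and FPKM in the sh-RUNX1 experiment, as mean ± SD. A log2 change on FPKM + 1 is smaller than that of FPKM itself for genes of low level.

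The 33 gene lists hold 750 symbols, of which 749 matched a gene. Lists with at least 5 tested members, 30 in the silencer and 29 in the sh-RUNX1 experiment, were compared with all other genes by camera with a preset correlation of 0.01. The adjusted p-values printed for lists are from camera unless another test is named. camera with an estimated correlation and fry, which tests whether a list's genes move on balance one way, were alternatives. Member counts are given over all tested genes and adjusted over the list alone.

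Named genes are RUNX1 and FOS, then, among genes past the threshold with non-overlapping groups, a mean of at least 1 in the higher group and an assigned symbol, the 12 largest rises and the 12 largest falls. Up to 4 members of each list with the smallest p-values past the threshold were added. Between experiments, the rule took the 6 genes with the smallest p in each direction of difference and the 6 largest shared changes per direction. Some genes that the rule names are not reported here. Genes named outside the rule are said to be chosen after their values were seen. RUNX1-IT1 has no entry in either table, so its level is not analysed here.

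Fold changes were compared by correlation across genes, by Fisher's exact test on the genes past the threshold in both experiments, and by a test of the difference per gene with the summed squared standard errors and Satterthwaite degrees of freedom. Correlations and Fisher p-values are across genes, which are not independent replicates.

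Alternatives fixed beforehand were DESeq2 1.42.0 and its size factors, no filter on low values and a minimum of 5 FPKM, pseudocounts of 0.1 and 0.5, quantile and median-of-ratios scaling, other variance priors, the replicate number as a block, a change of at least 1 on the log2 scale, and leaving out each library. Added after seeing the data were limma on the FPKM of the silencer table, edgeR and DESeq2 on the recovered reads of the sh-RUNX1 table, a minimum of 50 recovered reads, and the same test in both experiments.

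The tests were also tested on simulated data with the depth and spread of each table. edgeR recovered 69.1% of simulated silencer changes of 1 on the log2 scale and 95.9% of changes of 2, with 7.47% of its calls false. limma on the sh-RUNX1 design recovered 73.6% and 100%, with 3.55% false, and estimated the simulated changes as 0.826 and 1.62. The test of the difference recovered 85.3% with 6.3% of its calls false. Changed genes were drawn separately for each table, so this false share rests almost wholly on genes unchanged in both. It does not cover equal changes that edgeR on counts and limma on log2(FPKM + 1) estimate unlike, nor a control library that stands apart. Of 200 random lists camera called 2.5% at an unadjusted p under 0.05. Genes were simulated independently of one another. That rate therefore does not cover lists whose genes move together, such as the interferon-stimulated genes of the silencer experiment (estimated correlation 0.21).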

Results

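RNA of PANC-1 cells, an established line of human pancreatic cancer, was sequenced after 2 separate knockdowns. The first set 3 libraries of cells given a silencer against RUNX1-IT1, a long non-coding RNA transcribed from within the RUNX1 gene, against 3 libraries given a control silencer. The second set 2 libraries of cells with a hairpin vector against RUNX1, a transcription factor of blood and epithelial cells, against 3 with a control hairpin (sh-NC). The control silencer libraries held 13151373, 17905726 and 18316433 reads in genes and the RUNX1-IT1 silencer libraries 16788372, 17945529 and 19040332. The reads behind the sh-NC libraries came to 21781300, 21892036 and 24090966 and those behind the sh-RUNX1 libraries to 20723276 and 24419985. The labels do not say whether replicates are separate cultures, so the p-values may measure only the spread between these samples.

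RUNX1 (ENSG00000159216, hg38 chromosome 21, 34787801 to 36004667) was measured in every library, while RUNX1-IT1, which RefSeq places inside it (GRCh38.p14, 35037925 to 35039426), has no entry in either table. With the hairpin, RUNX1 stood at 2.08 and 1.74 FPKM in the 2 sh-RUNX1 libraries and at 2.81, 2.64 and 2.85 FPKM in sh-NC, a log2 change of -0.37 (SE 0.112, adjusted p = 0.13, n = 3 and 2). It was lower in both knockdown libraries than in any control. On recovered reads the hairpin libraries kept 69.5% of the control level (95% interval 55.5 to 87, edgeR adjusted p = 0.073). The adjusted p fell below the threshold without sh-NC library 3 (-0.36, 0.036) and with DESeq2 on recovered reads (-0.54, 0.031). With the silencer, RUNX1 stood at 61.1, 53.2 and 55.8 CPM against 74, 58.7 and 65.2 in the controls, a log2 change of -0.22 (SE 0.098, adjusted p = 0.21, n = 3 and 3).

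FOS (ENSG00000170345, chromosome 14, 75278774 to 75282230), an immediate-early gene of the AP-1 transcription factor that the series title names as induced by RUNX1-IT1, fell in both experiments. After RUNX1-IT1 silencing it was at 5.94, 3.48 and 4.65 CPM against 9.25, 9.38 and 16.9 in the controls, a log2 change of -1.35 (SE 0.294, adjusted p = 0.036, n = 3 and 3). After RUNX1 knockdown it was at 47.3 and 50.5 FPKM against 89.5, 89.6 and 81.9, a log2 change of -0.82 (SE 0.114, adjusted p = 0.012, n = 3 and 2). The 2 changes differed by -0.53 (SE 0.315, adjusted p = 0.37). The silencer call was lost without control library 2 (-1.49, adjusted p = 0.058) or 3 (-0.99, 0.065), without silencer library 1 (-1.55, 0.062), 2 (-1.17, 0.11) or 3 (-1.34, 0.1). It was also lost in limma on FPKM with a pseudocount of 1 (-0.60, 0.058) or 0.5 (-0.82, 0.053) or after quantile scaling (-0.45, 0.13). The hairpin call was lost without sh-NC library 1 (-0.80, 0.083) or sh-RUNX1 library 1 (-0.77, 0.22) or 2 (-0.86, 0.16).

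**Figure D1:**
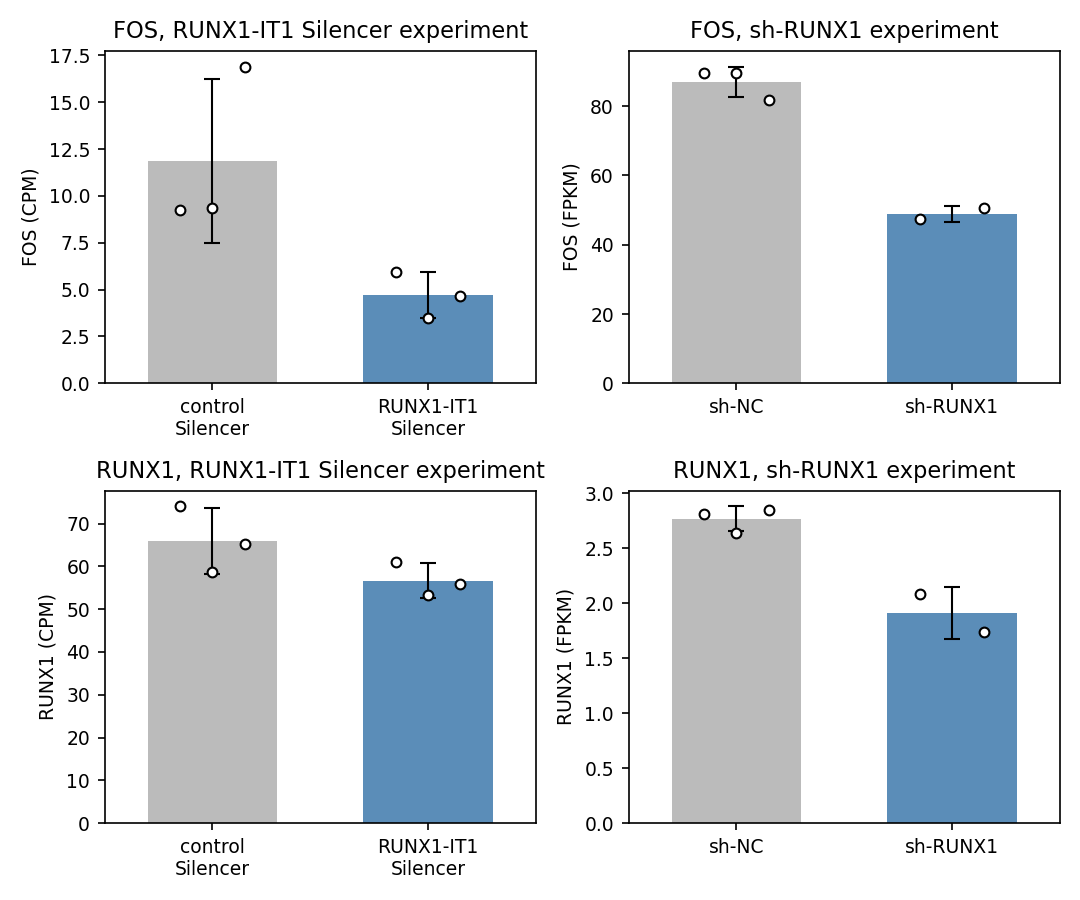
Levels of FOS and RUNX1 per library (points), with group means (bars) and SD (whiskers), in CPM for the silencer experiment and in FPKM for the sh-RUNX1 experiment. FOS lay at 3.48 to 5.94 CPM in silencer libraries against 9.25 to 16.9 in their controls, and RUNX1 at 1.74 and 2.08 FPKM in sh-RUNX1 libraries against 2.64 to 2.85 in sh-NC.

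The silencer comparison asks which genes change with the silencer against RUNX1-IT1, whose own level could not be checked. Of 34 interferon-stimulated genes 13 fell, of 29 immediate-early genes outside AP-1 5, and of 25 growth factor receptor and RAS/ERK feedback genes 5, and of 75 ribosomal protein genes 7 rose. With an estimated correlation the adjusted p of these lists was 0.24, 0.36, 0.24 and 0.43. CX3CL1, a membrane-bound chemokine, had the largest rise, from 15.95 ± 3.16 to 69.25 ± 6.76 CPM, 4.33-fold (log2 2.11, SE 0.146, adjusted p = 0.0012, n = 3 and 3). MUC5AC, a secreted gel-forming mucin, fell from 19.3 ± 2.07 to 2.29 ± 0.155 CPM (log2 -3.07, SE 0.128, adjusted p = 0.00025). ARC, an activity-induced immediate-early gene, fell from 37 ± 3.18 to 7.84 ± 0.502 CPM (log2 -2.24, SE 0.1, adjusted p = 0.00027).

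Of 15310 genes tested, 1268 passed, of which 435 rose and 833 fell (65.7% lower), and of the 282 with a change of at least 1 on the log2 scale 22 rose and 260 fell. DESeq2 called 686 rises and 759 falls (52.5% lower). Scaling on the reference genes gave 34 rises and 419 falls, and limma on FPKM 336 and 769. The groups did not overlap for 5135 genes (33.5%, against 10% by chance for 3 against 3), and 3996 genes had an unadjusted p under 0.05. The count was 549 without control library 2, 620 without control library 3, and 485, 365 and 544 without silencer library 1, 2 and 3. It was 675 over genes of at least 5 FPKM.

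Beside CX3CL1 (ENSG00000006210, chromosome 16, 57372458 to 57385048), large rises that no left-out library ended included those of SLC16A14, a member of the monocarboxylate transporter family (log2 1.46, SE 0.145), and CHAC1, a glutathione-degrading enzyme of the stress response (1.23, SE 0.093). PALM rose too (1.21, SE 0.141). RAB7B, TUBB3, KCNV1, NEU4, ZNF267, CEACAM6 and GPIHBP1 also rose, by 1.16 to 1.88 on the log2 scale. Each of these 7 calls was lost without at least 2 of the libraries (adjusted p from 0.05 to 0.12). TUBB3 and NEU4 were lost without control library 1, TUBB3, KCNV1, NEU4 and GPIHBP1 without control library 2, and RAB7B, KCNV1 and NEU4 without control library 3. Calls were lost without silencer library 1 for all but NEU4, without silencer library 2 for all 7, and without silencer library 3 for all but ZNF267. TUBB3 (adjusted p = 0.049), with control levels of 43, 32.3 and 110 CPM, also missed the threshold over genes of at least 5 FPKM (0.053), without the abundance trend (0.057) and with the robust prior (0.13), and KCNV1 in DESeq2 (0.093).

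The falls were steeper. RPL3L, a muscle paralog of the ribosomal protein L3, dropped from 152 to 4 reads over the 3 libraries of each group (log2 -5.20, SE 0.48), and EGLN3, an oxygen-sensing prolyl hydroxylase, from 95 to 5 (-4.25, SE 0.448). SCRT1, a neural repressor, dropped from 125 to 7 (-4.17, SE 0.377) and FRG2 from 105 to 10 (-3.44, SE 0.317). MUC5AC (ENSG00000215182, chromosome 11, 1157953 to 1201138), APOBR (-3.06), the aggrecanase ADAMTS4 (-2.94) and ENAM (-2.91) fell as well. CROCCP4 and ELAVL3 had 61 and 57 reads in the controls and none after silencing, at least 22.1-fold and at least 20.7-fold lower against a floor of 3 reads over the group. MUC17 fell from 49 to 4 reads (-3.60), a call lost without control library 2 (adjusted p = 0.061) or silencer library 1 (0.073).

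The interferon-stimulated genes were the list with the smallest p (adjusted p = 1.8e-13; adjusted p = 0.24 with an estimated correlation). Of 34 measured members 13 fell and none rose, with 21 falling adjusted over the list alone and a median log2 change of -0.58. OASL fell from 6.86 ± 0.92 to 2.25 ± 0.389 CPM (-1.61, SE 0.174), IFIT2 from 51.4 ± 1.06 to 24.7 ± 1.73 CPM (-1.06, SE 0.074), and the RNA sensors DDX58 and IFIH1 by 0.67 and 0.62 on the log2 scale. ISG15 and IFIT1, named after their values were seen, had changes of -0.20 and -0.14 (adjusted p = 0.33 and 0.54). The falling members numbered 11, 8 and 6 without control library 1, 2 or 3 and 7, 7 and 10 without silencer library 1, 2 or 3, while the list's median stayed between -0.46 and -0.67.

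Among 14 AP-1 subunits FOS, FOSB (-0.98, SE 0.107), BATF2, JDP2 and FOSL1 fell and JUND rose (0.44, SE 0.106, adjusted p = 0.048, named after its values were seen). The count was 6 falling and 2 rising adjusted over the list alone (list adjusted p = 0.029; adjusted p = 0.48 with an estimated correlation). Among 29 other immediate-early genes ARC, the nuclear receptors NR4A3 (-2.41, SE 0.306), NR4A2 (-1.86, SE 0.208) and NR4A1 (-1.04, SE 0.162), and EGR1 fell and SRF rose. The count was 12 falling and 1 rising adjusted over the list alone (list adjusted p = 1.1e-05; adjusted p = 0.36 with an estimated correlation). EGR1 (-0.70, SE 0.11) and SRF (0.36, SE 0.061) were named after their values were seen. The AP-1 list was lost without control library 3 (adjusted p = 0.18), without the filter on low counts (0.061), over genes of at least 5 FPKM (0.89), in limma on FPKM (0.59, or 0.65 after quantile scaling) and in fry (0.069). Without control library 1, 2 or 3 the falling AP-1 members numbered 5, 2 and 1 and the other falling immediate-early genes 9, 5 and 5. Without silencer library 1, 2 or 3 they numbered 1, 1 and 4, and 4, 3 and 5. NR4A1 was lost without silencer library 2 (0.056) and FOSB after quantile scaling (0.11). BATF2, JDP2 and FOSL1 were lost without control library 3 and silencer libraries 1 and 2 among others (0.056 to 0.085). JUND was lost without control library 2 (0.082) or 3 (0.083), any 1 silencer library (0.093 to 0.14) and after quantile scaling (0.054). SRF was lost without control library 2 (0.063) or silencer library 2 (0.058) or 3 (0.06), and EGR1 without silencer library 1 (0.054) or 2 (0.056).

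Growth factor receptor and RAS/ERK feedback genes had 5 falls among 25 members, with 13 falls and 2 rises adjusted over the list alone (adjusted p = 5.4e-05; adjusted p = 0.24 with an estimated correlation). HBEGF, an EGF receptor ligand, fell from 45.1 ± 4.44 to 18.4 ± 2.19 CPM (-1.29, SE 0.114), and NRG1, a ligand of ERBB receptors, by 0.51 on the log2 scale (SE 0.056). The receptor AXL fell too (-0.44, lost without silencer library 2, adjusted p = 0.051), as did ETV4 (-0.52, lost without control library 2 or 3 and silencer library 1 or 2, 0.054 to 0.059). The falls numbered 6, 3 and 3 without control library 1, 2 or 3 and 3, 2 and 4 without silencer library 1, 2 or 3. Among 22 NF-kappaB, cytokine and chemokine genes 4 fell, with 6 adjusted over the list alone (adjusted p = 0.002; adjusted p = 0.48 with an estimated correlation). The chemokines CCL5 (9.41 ± 0.874 to 3.57 ± 0.378 CPM, -1.40, SE 0.131) and CCL2 (-0.75, SE 0.091) fell in each left-out fit. LIF was lost without silencer library 2 (0.058) or 3 (0.051), and ICAM1 without control library 1 (0.051), 2 (0.089) or 3 (0.087) or silencer library 1 (0.081). The cytokine list itself was lost without control library 3 (0.068) and in fry (0.071).

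Cytosolic ribosomal protein genes rose slightly, 7 of 75, with 22 adjusted over the list alone and a median log2 change of 0.17 (adjusted p = 9e-09; adjusted p = 0.43 with an estimated correlation). Among them were RPS18 (533 ± 62.8 to 706 ± 19.1 CPM, 0.40, SE 0.083) and RPL10A (0.29, SE 0.055). RPS18 was lost without each library but control library 2 (adjusted p from 0.059 to 0.1) and after quantile scaling (0.067), and RPL10A without control library 3 or any 1 silencer library (0.059 to 0.093). The rises numbered 4, 3 and 1 without control library 1, 2 or 3 and 2, 1 and 3 without silencer library 1, 2 or 3. Under the scalings of DESeq2 and by quantiles the median kept its sign, with 20 rises in DESeq2 and 3 after quantile scaling. Scaling on the reference genes, which gave 34 rises over all genes against 435 in the main test, was not tried for this list. In fry the list missed the threshold (0.054). Mitochondrially encoded genes had 3 rises of 15, MT-CO3 (0.26, SE 0.056), MT-ND2 (0.18) and MT-RNR2 (0.22), with 7 adjusted over the list alone (adjusted p = 0.00043; adjusted p = 0.48 with an estimated correlation). Those rises numbered 2 without control library 1 and 0 without any other library (adjusted p for these 3 genes from 0.053 to 0.14). MT-ND2 and MT-RNR2 were lost over genes of at least 5 FPKM (0.062 and 0.074) and all 3 without the abundance trend (0.053 to 0.082). After quantile scaling the list's median was 0 (adjusted p = 0.84; fry 0.066). Mitochondrial transcripts took 4.58% to 4.83% of control reads and 4.94% to 5.42% of silencer reads.

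Replication-dependent histone genes had 4 falls of 11, and 4 adjusted over the list alone (adjusted p = 0.00074; adjusted p = 0.24 with an estimated correlation). HIST2H2BE fell from 13 ± 1.09 to 6.26 ± 0.184 CPM (-1.05, SE 0.104) and HIST1H4H by 0.90 on the log2 scale (SE 0.112). The falls numbered 4 without control library 1 and 2 without each of the other 5 libraries. Nuclear-retained and small structural RNAs had 2 falls of 12, and 2 adjusted over the list alone (adjusted p = 0.013; adjusted p = 0.24 with an estimated correlation; 0.16 over genes of at least 5 FPKM and 0.12 to 0.15 in limma on FPKM). These were KCNQ1OT1, a long antisense RNA of an imprinted locus (16.2 ± 1.58 to 6.73 ± 0.536 CPM, -1.27, SE 0.116), and NEAT1, the scaffold of paraspeckles (-0.41, SE 0.074). NEAT1 was lost without control library 3 (0.057) or silencer library 1 (0.067) or 2 (0.074). Epithelial genes had 3 rises of 19, with 9 rises and 2 falls adjusted over the list alone (adjusted p = 0.0039; adjusted p = 0.24 with an estimated correlation; 0.15 over genes of at least 5 FPKM and 0.055 after quantile scaling). The junction genes JUP (0.56, SE 0.094) and DSP (0.38, SE 0.058) were lost only without silencer library 2 among left-out libraries (0.056 for both). P-cadherin CDH3 (0.83, SE 0.141) was lost without control library 3 (0.057) or silencer library 1 (0.059) or 2 (0.06). None of the 3 passed without silencer library 2.

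Non-coding RNA fell more often than it rose. Among 551 genes annotated as antisense RNA 72 fell and none rose, and among 470 lincRNA genes 52 fell and 2 rose, against 636 falls and 417 rises of 12767 protein-coding genes. DESeq2 gave 58 antisense falls and no rise and quantile scaling 46 falls and 3 rises. Antisense falls numbered 60, 42 and 37 without control library 1, 2 or 3 and 36, 28 and 41 without silencer library 1, 2 or 3, and lincRNA falls 42, 23, 21, 19, 16 and 25 in the same order. Antisense RNA took 0.267% to 0.271% of control reads and 0.216% to 0.224% of silencer reads. A read was seen for 22357, 23556 and 23595 genes in the controls and for 21770, 21882 and 22103 in the silencer libraries.

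The other lists did not pass (adjusted p from 0.1 to 0.94), and their counts over all genes are followed in parentheses by those adjusted over the list alone. The RUNX family (9 members), S phase (32), G2/M (32) and unfolded protein response (20) genes had no member past the threshold by either count. Rises were found in 3 of 23 p53 targets, SESN1, SESN2 and BBC3 (3 rises, 2 falls), in 1 of 21 cholesterol genes (1 rise), in 1 of 21 glycolysis genes, ENO2 (0). So were rises in 1 of 20 MYC targets, FBL (0), and 1 of 14 reference genes, POLR2A (2 rises). Falls were found in 4 of 17 matrix proteases, among them ADAMTS1 (-0.96), MMP1 (-1.22) and MMP9 (5 falls), and in 4 of 19 oxidative stress genes, among them the ferritin light chain FTL, 1027 ± 82 to 557 ± 19.1 CPM (5 falls, 1 rise). A fall was also found in 1 of 20 mesenchymal genes, SNAI1 (4 falls, 2 rises), and in 1 of 22 DNA repair genes, PALB2 (1 fall). Members went both ways among 24 apoptosis regulators, with 4 rises, BMF largest at 1.10, and 2 falls, BCL2A1 among them (5 rises, 3 falls). The 24 ATF4 genes had 3 rises and 2 falls (4 and 4), 20 YAP targets 2 and 2 (4 and 2), and 20 TGF-beta genes 1 and 1 (4 and 4). The 18 heat shock genes had 1 and 1 (1 and 1), and 19 hypoxia genes 2 and 2 (3 and 4). With 1 library left out these lists held 0 to 4 rises and 0 to 6 falls, most without control library 1, and every left-out library changed at least 1 of the counts. FTL, ADAMTS1, SNAI1, PALB2, BMF and BCL2A1 kept their calls without each library. SESN1, SESN2, BBC3, ENO2, FBL, POLR2A, MMP1 and MMP9 lost it without silencer library 1 or 2, and all of these but MMP9 without silencer library 3 (adjusted p from 0.05 to 0.14). It was lost for BBC3, ENO2, POLR2A and MMP9 without control library 1, for SESN2, BBC3, ENO2, FBL, POLR2A and MMP9 without control library 2, and for SESN1, FBL, POLR2A and MMP9 without control library 3. ENO2, FBL and POLR2A were also lost in limma on FPKM (0.056 to 0.059). Median, mean and test differed in sign for the G2/M, p53, apoptosis, mesenchymal, TGF-beta, unfolded protein response, hypoxia and oxidative stress lists. Of the markers of other cells, 3 of 18 leukocyte, 6 of 18 endothelial and fibroblast, 4 of 20 pancreatic and 3 of 16 non-pancreatic genes were expressed enough to test. CD68, KDR (lost without silencer library 1, 0.057, or 2, 0.061) and CDX2 (lost without any 1 library, 0.056 to 0.13, and in DESeq2, 0.25) fell. Adjusted over the list alone there were 2 leukocyte falls, 1 endothelial rise and 1 fall, and 1 non-pancreatic fall.

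The hairpin comparison asks which genes change with the hairpin against RUNX1, which kept 69.5% of its control level on recovered reads (edgeR adjusted p = 0.073). Of 18 NF-kappaB, cytokine and chemokine genes 10 fell, of 26 immediate-early genes outside AP-1 8 and of 18 oxidative stress genes 7. With an estimated correlation the adjusted p of these lists was 0.22, 0.4 and 0.22. ICAM1, an adhesion molecule induced by NF-kappaB, fell from 76.7 ± 10.7 to 23.1 ± 0.187 FPKM (log2 -1.68, SE 0.143, adjusted p = 0.0025, n = 3 and 2). EGR1, an immediate-early transcription factor, fell from 439 ± 43.9 to 150 ± 1.07 FPKM (-1.54, SE 0.125, adjusted p = 0.0023). MYL9, a myosin light chain of contractile cells, rose from 13 ± 2.6 to 72.1 ± 0.628 FPKM (2.40, SE 0.164, adjusted p = 0.0023), and TNS4, a focal adhesion gene, from 0.731 ± 0.0969 to 6.1 ± 0.548 FPKM (2.04, SE 0.118).

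Of 11903 genes tested, 426 passed, of which 217 rose and 209 fell, and 60 and 40 of them changed by at least 1 on the log2 scale. The groups did not overlap for 4555 genes (38.3%, against 20% by chance for 3 against 2), and 2129 had an unadjusted p under 0.05. The count rests on the libraries: it was 78, 263 and 2885 without sh-NC library 1, 2 or 3, and 45 (36 rises and 9 falls) and 47 (41 and 6) without sh-RUNX1 library 1 or 2, fits in which the lone library is assumed to vary like the others. It was 123 without the filter on low FPKM (84 rises and 39 falls), and 711 and 799 for edgeR and DESeq2 on recovered reads (367 and 344, and 359 and 440). Without sh-NC library 3 it held 1288 rises and 1597 falls. Library 3 of sh-NC stood apart from the other controls (Pearson r of log values 0.982 and 0.979, against 0.993 between those 2). Between those 2 controls and the sh-RUNX1 libraries r was 0.9809 to 0.9825. By this measure library 3 differed from the other controls about as much as the sh-RUNX1 libraries did.

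MYL9 (ENSG00000101335, chromosome 20, 36541484 to 36551447) and TNS4 passed in every left-out fit. So did SLC4A11, a membrane transporter of the bicarbonate transporter family (1.81, SE 0.15), the tubulin gene TUBA4A (1.77, SE 0.128), the ion channel TRPA1 (1.73, SE 0.122), LRRN2 (1.69, SE 0.138) and SPDEF, an epithelial ETS factor (1.68, SE 0.138). The pseudocount shrinks changes at low levels. TRPA1 went from 0.207 to 3 FPKM and SPDEF from 0.202 to 2.83 FPKM, with a log2 change of 3.85 for each in edgeR on recovered reads. The collagen gene COL1A1 rose from 24.2 ± 4.14 to 74.7 ± 3.49 FPKM (1.60, SE 0.156), a call lost without sh-RUNX1 library 1 (adjusted p = 0.051) or 2 (0.054). Falls that passed in every left-out fit were those of ICAM1 (ENSG00000090339, chromosome 19, 10270835 to 10286615), EGR1 (ENSG00000120738, chromosome 5, 138465490 to 138469315), and the chemokines CXCL2 (10.7 ± 1.21 to 2.64 ± 0.44 FPKM, -1.68, SE 0.135) and CCL5 (-1.63, SE 0.139). RHEB, a GTPase that activates mTORC1 (28.7 ± 1.24 to 9.28 ± 0.723 FPKM, -1.53, SE 0.113), and the proteoglycan SRGN (-1.33, SE 0.104) did so as well. CXCL8, METRNL and ZNF213 fell by 1.32 to 1.48 on the log2 scale and were lost without sh-RUNX1 library 1 (0.061 to 0.071) or 2 (0.053 to 0.1), ZNF213 also without the filter on low FPKM (0.056). Short genes were also among the largest changes, with few reads behind them: MIR210 36 control reads and 4 knockdown reads, SNORD117 20 and 3, MT-TF 3 and 12, MIR6746 1 and 9. There were none in the controls for SNORD114-21 (6 reads, at least 3-fold higher) and TRBJ2-5 (4 reads, at least 2-fold higher). Of these, only TRBJ2-5 passed without each library. MIR6746 and SNORD117 were lost without either sh-RUNX1 library, MT-TF without sh-NC library 1 or either sh-RUNX1 library. SNORD114-21 was lost without sh-NC library 1 and MIR210 without sh-RUNX1 library 2 (adjusted p from 0.053 to 0.25), and these 5 without the filter on low FPKM (0.064 to 0.17).

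Of 18 NF-kappaB, cytokine and chemokine genes 10 fell and none rose, with 13 falls and 1 rise adjusted over the list alone and a median log2 change of -0.80 (adjusted p = 1.8e-12; adjusted p = 0.22 with an estimated correlation). CXCL2, ICAM1, CCL5 and CXCL8 led it, and the falls numbered 8, 9 and 15 without sh-NC library 1, 2 or 3 and 3 without either sh-RUNX1 library. Of 26 other immediate-early genes 8 fell, EGR1 and EGR2 (1.4 to 0.131 FPKM, -1.08, SE 0.121, and -3.40 in edgeR on recovered reads) among them. NR4A2, which fell after RUNX1-IT1 silencing, rose from 1.47 ± 0.206 to 3.4 ± 0.0266 FPKM (0.84, SE 0.12). The count was 10 falls and 1 rise adjusted over the list alone (adjusted p = 2e-05; adjusted p = 0.4 with an estimated correlation). Of 13 AP-1 subunits FOS, FOSB (50.1 ± 2.92 to 24.2 ± 0.477 FPKM, -1.02, SE 0.113) and JUN (-1.08, SE 0.13) fell, with 5 falls adjusted over the list alone (adjusted p = 3.6e-05; adjusted p = 0.62 with an estimated correlation; fry 0.086). Without sh-NC library 1, 2 or 3 and sh-RUNX1 library 1 or 2, in that order, the immediate-early falls numbered 2, 4, 14, 2 and 1, and the AP-1 falls 1, 3, 10, 0 and 0. FOSB was lost without either sh-RUNX1 library (0.11), and JUN without sh-NC library 1 (0.052), sh-RUNX1 library 1 (0.12) or 2 (0.14) and without the filter on low FPKM (0.053). EGR2 was lost without sh-RUNX1 library 2 (0.058), and NR4A2 without sh-NC library 1 (0.071), sh-RUNX1 library 1 (0.17) or 2 (0.16) and without the filter (0.077).

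Oxidative stress genes had 7 falls of 18, with 9 adjusted over the list alone (adjusted p = 1.2e-08; adjusted p = 0.22 with an estimated correlation). Among them were the quinone reductase NQO1 (81.2 ± 6.07 to 41.9 ± 0.693 FPKM, -0.94, SE 0.118), SRXN1 (-0.86), TXNRD1 (-0.91) and HMOX1 (-0.88). Glycolysis genes had 3 falls of 21, PFKP (222 ± 34 to 112 ± 1.08 FPKM, -0.96, SE 0.151), PFKL (-0.87) and PFKFB4 (-0.84), with 5 adjusted over the list alone (adjusted p = 0.00037; adjusted p = 0.66 with an estimated correlation; fry 0.21). Growth factor and RAS/ERK genes had 5 falls of 21, among them DUSP6 (-0.74), DUSP5 (-0.75) and AREG (-0.67), and 1 rise, HBEGF (0.66, SE 0.107). The count was 6 falls and 3 rises adjusted over the list alone (adjusted p = 0.017; adjusted p = 0.34 with an estimated correlation). Interferon-stimulated genes had 2 falls of 22, UBE2L6 (-1.10, SE 0.137) and IRF1 (-0.74, SE 0.124), with 3 adjusted over the list alone (adjusted p = 0.0015; adjusted p = 0.22 with an estimated correlation). Ribosomal protein genes had no member past the threshold of 74, nor any adjusted over the list alone, with a median of -0.19 (adjusted p = 2.4e-08; adjusted p = 0.66 with an estimated correlation; fry 0.21). DESeq2 on recovered reads called 3 falls and quantile scaling 4. Without sh-NC library 1, 2 or 3 and sh-RUNX1 library 1 or 2, in that order, the falls numbered 0, 5, 12, 0 and 0 for oxidative stress, 0, 2, 11, 0 and 0 for glycolysis, and 0, 4, 11, 0 and 0 for growth factor genes. They numbered 0, 1, 7, 0 and 0 for interferon-stimulated and 0, 0, 42, 0 and 0 for ribosomal protein genes. Each gene named in this group was lost without sh-NC library 1 (adjusted p from 0.061 to 0.17) and without either sh-RUNX1 library (0.11 to 0.37), and PFKL, DUSP5, HBEGF and IRF1 also without sh-NC library 2 (0.05 to 0.071). All but NQO1, SRXN1, DUSP6 and AREG were lost without the filter on low FPKM (0.055 to 0.14).

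Lists that rose did so with few members. Replication-dependent histone genes had 2 rises of 9, HIST1H2BC (1.87 ± 0.386 to 4.37 ± 0.137 FPKM, 0.91, SE 0.136) and HIST1H2BK (0.66, SE 0.121), with 6 adjusted over the list alone (adjusted p = 0.00014; adjusted p = 0.22 with an estimated correlation). TGF-beta response genes had 3 rises of 18, the differentiation inhibitors ID2 (2.41 ± 0.226 to 5.79 ± 0.297 FPKM, SE 0.112) and ID3 (1.04, SE 0.16) and LTBP2 (0.79), and 1 fall, THBS1 (-0.82). The count was 7 rises and 1 fall adjusted over the list alone (adjusted p = 0.011; adjusted p = 0.48 with an estimated correlation; 0.13 without the filter on low FPKM). Mesenchymal genes had 2 rises of 14, COL1A1 and SPARC (0.80, SE 0.112), with 4 rises and 1 fall adjusted over the list alone (adjusted p = 0.044; adjusted p = 0.48 with an estimated correlation). This list was lost without sh-NC library 3 (0.15), sh-RUNX1 library 1 (0.065) and without the filter on low FPKM (0.45). Unfolded protein response genes had no member past the threshold of 20, nor any adjusted over the list alone, with a median of 0.15 (adjusted p = 0.016; adjusted p = 0.4 with an estimated correlation). They were lost without sh-RUNX1 library 2 (0.095). Without sh-NC library 1, 2 or 3 and sh-RUNX1 library 1 or 2, in that order, the rises numbered 0, 1, 5, 0 and 0 for histones, 1, 3, 9, 0 and 0 for TGF-beta, 1, 2, 4, 0 and 0 for mesenchymal and 0, 0, 5, 0 and 0 for unfolded protein response genes. The single genes were lost without either sh-RUNX1 library (adjusted p from 0.051 to 0.41) and all but ID2 and COL1A1 without sh-NC library 1 (0.06 to 0.11), HIST1H2BK also without sh-NC library 2 (0.079). HIST1H2BC, HIST1H2BK, ID3, LTBP2 and SPARC were lost without the filter on low FPKM (0.053 to 0.087). None of the called lists of either experiment passed with an estimated correlation.

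The other lists did not pass after RUNX1 knockdown (adjusted p from 0.1 to 0.86), with the count adjusted over the list alone in parentheses. No member passed of the RUNX family (8 members; 1 rise, 2 falls), G2/M (31; 0), matrix protease (14; 2 rises, 1 fall), YAP (18; 3 rises, 1 fall), ATF4 (22; 0), heat shock (18; 0), cholesterol (21; 0), MYC target (20; 0), DNA repair (19; 0) and reference (14; 1 rise) lists. Of 31 S phase genes MCM6 rose and UHRF1 fell (1 and 1), and of 22 p53 targets PLK2 and GDF15 fell (2 falls). Of 23 apoptosis regulators BMF rose and BCL2L2 fell (1 rise, 2 falls), and of 18 epithelial genes CDH3 rose and CLDN1 fell (3 rises, 4 falls). Of 15 hypoxia genes NDRG1 and STC1 rose and ANGPTL4 and BNIP3 fell (2 rises, 4 falls). Of 15 mitochondrially encoded genes MT-CYB rose (2 rises, 1 fall), and of 7 nuclear-retained RNAs GAS5 fell (1 and 1). Each of these genes was lost without either sh-RUNX1 library and without sh-NC library 1 (adjusted p from 0.071 to 0.5), MCM6, GDF15, NDRG1, STC1, BNIP3, MT-CYB and GAS5 also without sh-NC library 2 (0.06 to 0.098), and all but UHRF1 without the filter on low FPKM (0.053 to 0.21). CLDN1 was also lost with median-of-ratios scaling (0.055). Without sh-NC library 3 each of these lists had 1 to 5 members past the threshold in at least 1 direction. Median, mean and test differed in sign for S phase, epithelial and heat shock genes. Of the markers of other cells, 1 leukocyte, 2 endothelial and fibroblast, 4 pancreatic and 1 non-pancreatic gene could be tested. COL1A1 and ESAM rose (2 rises) and SYP fell (2 falls), and 1 leukocyte gene rose adjusted over the list alone. ESAM and SYP were lost without sh-NC library 1 (0.083 and 0.13), either sh-RUNX1 library (0.17 to 0.37) or the filter on low FPKM (0.081 and 0.13) and SYP without sh-NC library 2 (0.092).

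Between sh-NC library 3 and the other 2 controls the list medians differed by 0.33 on the log2 scale for G2/M genes, 0.42 for DNA repair genes, -0.33 for glycolysis genes, -0.28 for AP-1 subunits and -0.22 for ribosomal protein genes. For NF-kappaB genes they differed by -0.21, and between sh-RUNX1 and those 2 controls by -0.83. The latter difference was 0.07 for G2/M genes, 0.05 for DNA repair genes, -0.26 for glycolysis genes, -0.36 for AP-1 subunits and -0.27 for ribosomal protein genes.

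**Figure D2:**
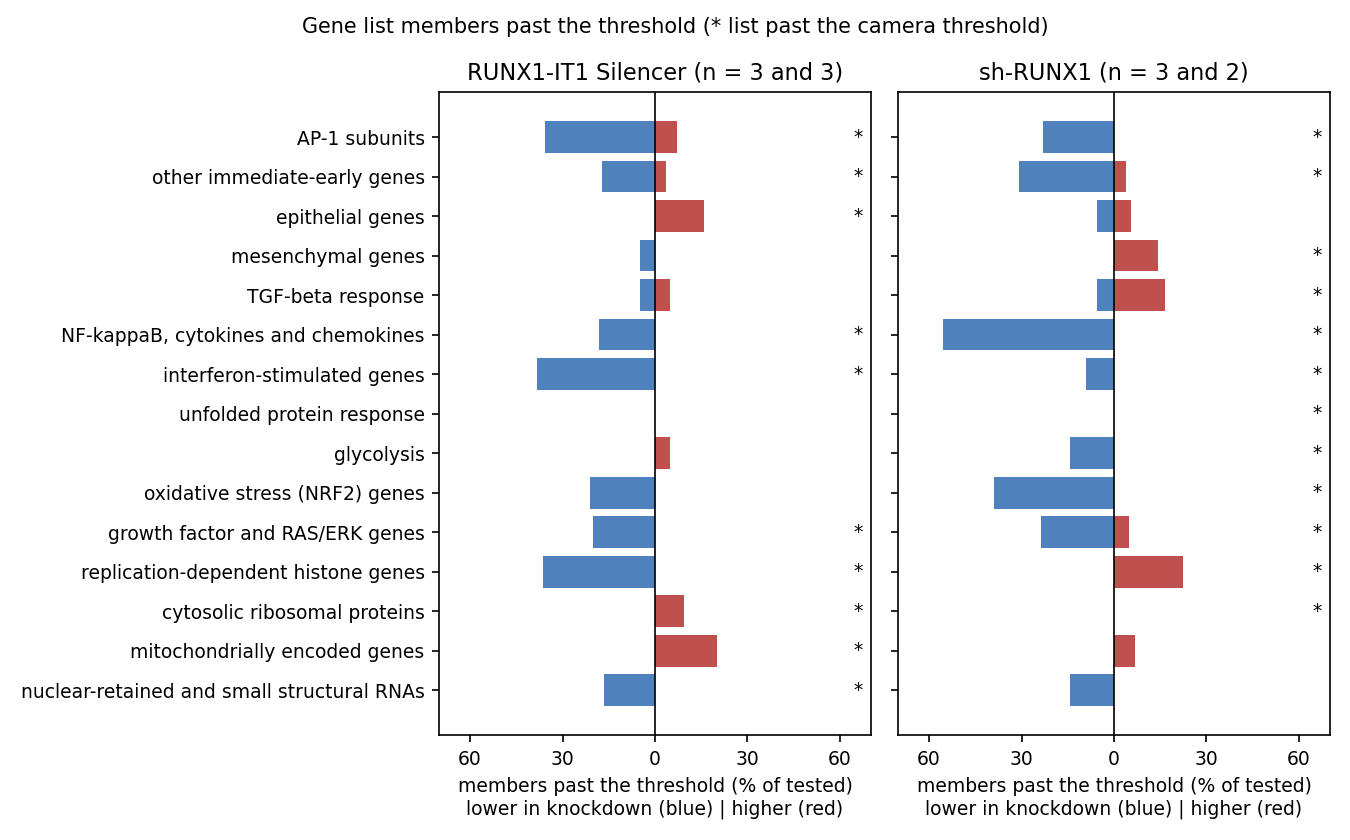
Share of tested members past the threshold, lower in the knockdown (blue, to the left) or higher (red, to the right), for each list past the camera threshold (star) in at least 1 experiment. In the silencer experiment 13 of 34 interferon-stimulated genes fell, in the sh-RUNX1 experiment 10 of 18 NF-kappaB genes, and no star remained with an estimated correlation.

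Whether both knockdowns moved the same genes was compared across the 11245 genes tested in both. The chemokine CCL5 (-1.40 with the silencer and -1.63 with the hairpin) and the proteoglycan SRGN (-1.05 and -1.33) fell in both experiments and MYL9 rose in both (0.72 and 2.40), in every fit with 1 library left out. FOSB (-0.98 and -1.02), FOS, NFKBIZ, a regulator of NF-kappaB targets (-0.81 and -0.85), and PTX3 (-0.79 and -1.21) also fell in both. SNCG (0.98 and 1.12), CDH3 (0.83 and 0.82), NES (0.74 and 1.23), SLC2A12 (0.75 and 0.86) and KRT86 (0.95 and 0.73) rose. RASD1, a RAS-related GTPase, went opposite ways, from 14.9 to 5.04 CPM with the silencer (-1.57, SE 0.098) and from 2.34 to 8.11 FPKM with the hairpin (1.46, SE 0.129). So did the Notch ligand DLL4 (-1.02 and 1.01), HBEGF (-1.29 and 0.66) and EPAS1, a hypoxia-inducible factor (-0.48 and 0.96). UBP1 rose with the silencer and fell with the hairpin (0.74 and -0.57). In the silencer experiment NFKBIZ was lost without silencer library 2 or 3, and PTX3 without control library 3 or silencer library 2 or 3. SLC2A12 and KRT86 were lost without control library 2 or 3, silencer library 2 or 3, and KRT86 also without silencer library 1, and EPAS1 without control library 2 or silencer library 2 (adjusted p from 0.051 to 0.088). In the hairpin experiment each gene of this group but CCL5, SRGN, MYL9 and RASD1 was lost without either sh-RUNX1 library (0.053 to 0.51), and RASD1 without sh-RUNX1 library 2 (0.051). Lost were also SNCG, CDH3, SLC2A12, KRT86, FOS, NFKBIZ, HBEGF and UBP1 without sh-NC library 1 (0.056 to 0.15), the last 2 also without sh-NC library 2 (0.05 and 0.074).

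Across all genes the log2 changes were almost unrelated (Pearson r = 0.019, Spearman rho = 0.004). Past the threshold in both were 77 genes, 50 in the same direction and 27 in opposite directions. The shared rises were 22 where 6.61 would arise independently (Fisher's exact test, two-sided, p = 7.2e-07, adjusted over the 4 tests 1.4e-06) and the shared falls 28 against 9.13 (Fisher's exact test p = 1.1e-07, adjusted 4.3e-07). Genes that fell with the silencer and rose with the hairpin were 19 against 8.75 (Fisher's exact test p = 0.0013, adjusted 0.0018). The reverse were 8 against 6.9 (Fisher's exact test p = 0.56). The change differed between experiments for 718 genes (6.39%, difference test, 2489 at an unadjusted p under 0.05), 343 of them higher and 375 lower with the silencer. Without control library 2 or 3 and silencer library 1, 2 or 3, in that order, 33, 33, 31, 20 and 30 genes were shared in the same direction and 13, 13, 12, 10 and 16 in opposite directions. Without sh-NC library 1, 2 or 3 and sh-RUNX1 library 1 or 2 they were 12, 33, 176, 5 and 5, and 4, 14, 139, 2 and 1. The differing genes were 325 without sh-NC library 1, 2672 without sh-NC library 3, and 116 and 115 without sh-RUNX1 library 1 and 2. The silencer fold changes are from counts and the hairpin ones from log2(FPKM + 1), and with edgeR on reads in both the opposite genes were 48. The experiments also differ in delivery, by silencer or hairpin vector, and in their libraries. Ribosomal protein genes took 2.32% to 2.81% of reads in the silencer experiment and 7.14% to 8.34% in the sh-RUNX1 experiment. Differences between the experiments therefore cannot be laid to the target alone.

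**Figure D3:**
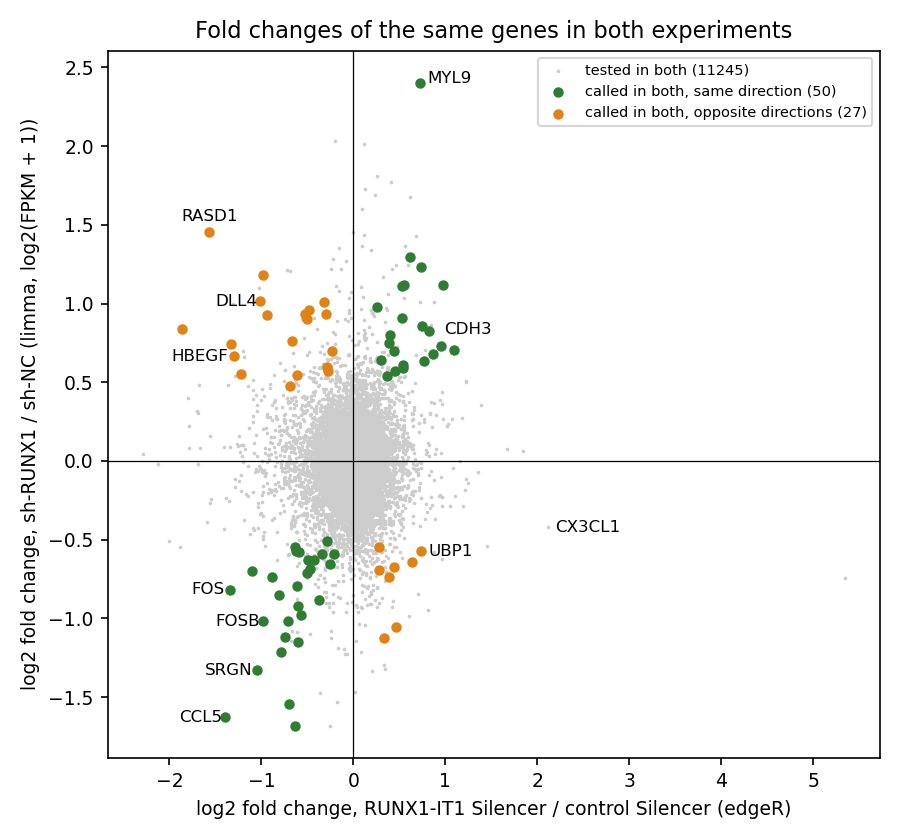
Log2 fold change of each of the 11245 genes tested in both experiments, with the RUNX1-IT1 silencer (x axis, edgeR) and with sh-RUNX1 (y axis, limma on log2(FPKM + 1)), grey points for all genes, green for the 50 past the threshold in both in the same direction and orange for the 27 in opposite directions. MYL9 lies at 0.72 and 2.40, CCL5 at -1.40 and -1.63, and RASD1 at -1.57 and 1.46.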

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

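Chosen only after the results were seen were the tests of scaling, genomic DNA and unspliced RNA for the excess of falling genes and, for the interferon-stimulated genes, those of the size of the fall and of the interferon genes, and the split of the position of sh-NC library 3 by size of change.

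After RUNX1-IT1 silencing 833 genes fell and 435 rose, and among changes of at least 1 on the log2 scale 260 fell and 22 rose. Scaling between libraries left the share of falls among the larger changes at 90% or more under each of 4 alternatives, of which 2 also change the test and 1, quantile scaling of FPKM, kept 36 falls and 4 rises, while over all calls 64% were lower in edgeR with the size factors of DESeq2, 65.7% in the main test and 52.5% in DESeq2 itself, and 419 of them fell and 34 rose in edgeR scaled on the reference genes. The median log2 change of all genes was -0.0017 in the main test, -0.067 in DESeq2 and 0.016 after quantile scaling. Shifts of that size could hardly turn a change of at least 1, so the share among the larger changes cannot decide on scaling. Reads of genomic DNA in the controls, judged from 353 olfactory receptor genes (103 reads against 80), would give 0.16% of the drop of the median falling gene. Unspliced RNA of overlapping genes could add to genes inside others, and 36.9% of the 260 overlapped a gene of at least 10 CPM (exact binomial interval 31 to 43.1), against 31.9% of uncalled genes of like expression. Such an overlap was found for 96 of the 260 and for 28 of the 133 that are protein coding, so the share was higher among the others. The uncalled genes were not split in this way, so unspliced RNA stays open for those others. A response to the loss of RUNX1-IT1 and an effect of either silencer outside its target stay open as hypotheses, since there is no untreated sample and no other silencer.

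Interferon-stimulated genes fell after RUNX1-IT1 silencing, 13 of 34, with a median log2 change of -0.58. With an estimated correlation of 0.21 the list did not pass (camera adjusted p = 0.24). Only 6 of the 13 stayed past the threshold without control library 3, under the bound of 7 set beforehand, and 7 to 10 without the others. Over all genes the count without control library 3 went from 1268 to 620. Dependence of single calls on 1 library and the smaller number of samples therefore cannot be told apart by this count. The list's median log2 change stayed between -0.46 and -0.67 whichever library was left out. The upper end of its bootstrap interval was at most -0.294 over the 6 fits with 1 library left out. That interval resamples the genes of the list as if they were independent and holds no spread between libraries. An interferon response set off by the control silencer and a loss of interferon signalling with the knockdown cannot be told apart: the interferon genes had at least 2.74 CPM in all in each control library and at most 1.13 in each silencer library, and the control silencer's own effect stays open for lack of an untreated sample.

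Library 3 of sh-NC stood apart from the other controls, and the number of genes past the threshold went from 426 to 2885 without it. A mislabelled library was to lie above 0.75 between the other controls (0) and the sh-RUNX1 libraries (1). The median position of library 3 over those 2885 genes was 0.495 (bootstrap interval 0.456 to 0.531). That lies under the bound, but the interval reaches past the 0.5 set against mislabelling. Over the 129 of these genes with a log2 change of at least 1 the position was 0.113 (0 to 0.197), near the other controls. Over the other 2756 it was 0.527 (0.494 to 0.561). The genes were picked by the same libraries that set 0 and 1. That choice can draw even a true control away from 0, most where changes are small. The position over all 2885 or over the 2756 genes therefore cannot decide on mislabelling. The intervals also resample genes as if they were independent. Over all tested genes, the Pearson r of log values of library 3 was 0.9739 and 0.9774 with the sh-RUNX1 libraries. It was 0.9823 and 0.9794 with the other controls, and 0.994 between the 2 sh-RUNX1 libraries. These values argue against a library like those 2 under a wrong label. Scaling leaves the difference in place, with a spread around the other 2 controls 1.83 times that between them after quantile normalization and 1.88 times before. A small admixture and a control culture in another state stay open and were not tested.

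The 10 splits of the 6 silencer libraries into 3 and 3 are too few for a share under 0.05. Of these, 1 split, the real one with 1268 genes, reached that many, and the highest of the others gave 10.

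The response differed between the experiments for 718 genes in the test of the difference of log2 changes, with the silencer minus the hairpin given for each gene below. Since delivery and libraries also differ between the experiments, these differences cannot be laid to the target alone. The difference was 2.53 for CX3CL1 (SE 0.214, adjusted p = 1.3e-05), which with the hairpin did not pass in the main test and did without sh-NC library 3 (0.011). It was 1.99 for SLC16A14 (SE 0.202, adjusted p = 5.9e-05), which likewise did not pass in the main test and did without sh-NC library 3 (0.044). For UBP1 it was 1.31 (SE 0.136, adjusted p = 0.00012), and for RHEB 1.36 (SE 0.128, adjusted p = 0.00012), with changes of -0.17 and -1.53. Lower with the silencer were RASD1 by -3.02 (SE 0.162, adjusted p = 2.1e-07), HBEGF by -1.96 (SE 0.156, adjusted p = 1.3e-05), DLL4 by -2.03 (SE 0.198, adjusted p = 5.6e-05) and EPAS1 by -1.44 (SE 0.126, adjusted p = 2.3e-05). The difference was -1.72 for EMP1 (SE 0.136, adjusted p = 1.3e-05), with changes of -1.56 and 0.16, and -1.84 for PARD6G-AS1 (SE 0.166, adjusted p = 2.2e-05), with -1.36 and 0.48, with the hairpin not past the threshold in the main test and past it without sh-NC library 3 (0.03). These 10 differences stayed past the threshold in each alternative and each fit with 1 library left out. The number of differing genes was 325 without sh-NC library 1, 2672 without sh-NC library 3, and 116 and 115 without sh-RUNX1 library 1 and 2.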

How the results depend on the processing

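No list or named gene past the threshold turned its direction under the alternatives and left-out fits run for it, while the correlation between the experiments, near 0, changed its sign. Tests on FPKM of the silencer table, on recovered reads of the sh-RUNX1 table and with the same tool in both experiments were added after seeing the data. Where no cause is named below, the cause was not tested. The labels do not say that replicate numbers pair the samples. The correlation of residuals between equal numbers was 0.033, -0.043 and 0.04 in the silencer experiment. In the sh-RUNX1 experiment it was 0.014 and -0.17 for the title number and 0.17 and 0.13 for the code. Residuals around the mean of 2 sh-RUNX1 libraries are each other's with the sign turned, so these last values cannot check a pairing. With 2 sh-RUNX1 libraries, leaving out 1 leaves a lone library, and each left-out fit has fewer samples.

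The 1268 genes of the silencer experiment became 675 over genes of at least 5 FPKM (fewer genes tested), 462 with a replicate block and 282 with a change of at least 1, and 365 to 1343 with 1 library left out. The 426 of the sh-RUNX1 experiment became 123 with no filter on low FPKM, 2812 with a block by title number, 745 by the code, 100 with a change of at least 1, 711 in edgeR and 799 in DESeq2 on recovered reads, and 45 to 2885 with 1 library left out.

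RUNX1 after its knockdown passed the threshold in 3 settings. These were the title block (-0.36, adjusted p = 0.018), the fit without sh-NC library 3 (-0.36, 0.036) and DESeq2 on recovered reads (-0.54, 0.031). The title block and the fit without sh-NC library 3 both keep that library out of the change, so they are not separate settings in this respect. With 1 library left out RUNX1 ranged from -0.46 to -0.29. After RUNX1-IT1 silencing it ranged from -0.29 to -0.13. FOS after RUNX1-IT1 silencing was at -1.32 with the replicate block (adjusted p = 0.06), -0.60 in limma on FPKM with a pseudocount of 1, -0.82 with 0.5 and -0.45 after quantile scaling, smaller by construction for a low level, and ranged from -1.55 to -0.99 with 1 library left out. After RUNX1 knockdown FOS ranged from -0.86 to -0.77.

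With an estimated correlation 0 lists passed in either experiment. In the silencer experiment 6 lists passed over genes of at least 5 FPKM and 6 after quantile scaling. With a block, the mesenchymal list (title number, adjusted p = 0.07) and the unfolded protein response list (code, 0.088) were lost in the sh-RUNX1 experiment, and in the silencer experiment CROCCP4 (0.05), MUC17 (0.05) and ELAVL3 (0.052) of the largest falls and RAB7B (0.063), KCNV1 (0.098), CEACAM6 (0.061) and GPIHBP1 (0.071) of the largest rises. Of the called silencer genes tried under each alternative, 33 were lost with that block (adjusted p from 0.05 to 0.12) and 61 kept. Among the other genes lost were BATF2 (0.058), BBC3 (0.055), CDH3 (0.053), CDX2 (0.11), DSP (0.05), ENO2 (0.1), ETV4 (0.057), FBL (0.098), ICAM1 (0.057), KDR (0.061), MMP9 (0.068), MT-CO3 (0.073), MT-ND2 (0.11), MT-RNR2 (0.12), POLR2A (0.086), RPL10A (0.054) and SESN1 (0.07). With the block by the code BNIP3 (0.064), GAS5 (0.084) and MT-CYB (0.052) were lost in the sh-RUNX1 experiment.

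The correlation of 0.019 between the experiments was 0.033 over silencer genes of at least 5 FPKM, 0.03 after quantile scaling of the silencer FPKM, 0.004 with no filter on sh-RUNX1 values, 0.053 over sh-RUNX1 values of at least 5 FPKM, 0.031 after their quantile scaling, -0.004 with the title block, -0.005 with edgeR and -0.007 with DESeq2 on recovered reads, -0.005 with edgeR in both, and -0.004 to 0.033 with 1 library left out. The 718 differing genes became 348 over silencer genes of at least 5 FPKM and 2231 with the title block, and 115 to 2672 with 1 library left out.

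The 50 genes shared in the same direction became 31 over silencer genes of at least 5 FPKM, 27 with the silencer block, 5 with silencer changes of at least 1, 12 with no filter on sh-RUNX1 values, 160 with the title block, 15 with sh-RUNX1 changes of at least 1 and 89 with DESeq2 on recovered reads, and 5 to 176 with 1 library left out. The 27 in opposite directions became 11 with the silencer block, 6 with silencer changes of at least 1, 5 with no filter, 131 with the title block, 6 with sh-RUNX1 changes of at least 1, 48 with edgeR and 51 with DESeq2 on recovered reads and 48 with edgeR in both, and 1 to 139 with 1 library left out.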

Other observations

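In this part the tests of a local effect, of a chromosome segment and of short genes were chosen only after the result was seen, as were the genes named.

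Of 18 tested genes within 1 Mb of RUNX1, CBR1, a carbonyl reductase gene beside it (chromosome 21, 36069941 to 36073166), rose after RUNX1-IT1 silencing (log2 0.80, SE 0.131, adjusted p = 0.014), a call lost without silencer library 2 (0.056). The pseudogene MEMO1P1 fell (-0.48, adjusted p = 0.039), a call lost without any 1 library (0.064 to 0.11). After RUNX1 knockdown CBR1 changed by -0.32 (adjusted p = 0.17), and the difference between the experiments was 1.13 (SE 0.171, adjusted p = 0.0013). A local effect of the knockdown on genes around RUNX1 may be asked from these: the median absolute log2 change of the 18 genes, 0.207, lay at percentile 83.2 of 10000 random lists of like expression, under the bound of 95, which leaves a local effect open.

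MED29, a subunit of the Mediator complex (chromosome 19, 39391303 to 39400637), fell from 1054 to 305.1 CPM after RUNX1-IT1 silencing (log2 -1.79, SE 0.044, adjusted p = 1.1e-05), and by 1.77 to 1.80 on the log2 scale without each library. With the hairpin it changed by 0.08 (adjusted p = 0.79), and the difference was -1.87 (SE 0.129, adjusted p = 5.9e-05). Loss of a chromosome segment could lower it together with its neighbours, but the 20 nearest expressed genes had a median log2 change of -0.042 (-3.02 to 0.51). An effect of the silencer on MED29 RNA itself stays open as a hypothesis and was not tested.

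Of the 426 genes past the threshold after RUNX1 knockdown, 26 are shorter than 200 bases. Few reads behind a high FPKM may account for them: a median of 12.5 reads over the 5 libraries stood behind these genes, against 2960 for the other 400, and 22 had under 50. Of the 26, edgeR could test 5 on the recovered reads, and 0 of these passed.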
